A study of Drosophila melanogaster with 2 samples.

How the data were processed

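Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster prepupae (1 day) expressing Gug fused to eGFP, with an antibody to GFP, per the labels. The labels give 2 biological replicates of this single group, chromatin broken by sonication, and possible controls in a separate experiment. The replicate numbers are those of the labels.

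The deposited files are peak lists on dm6, per the file headers and labels. For each replicate, and for both replicates together, the authors deposited a ranked list and a thresholded list, the latter selected by the irreproducible discovery rate (IDR), which measures how reproducibly a peak ranks between 2 replicates or pseudoreplicates. The aligner, peak caller and IDR settings were not given in the sources used here. In every list, the thresholded peaks were the ranked peaks with a global IDR of 0.01 or less, as tested on the files, minus 73 to 104 peaks that the thresholded lists leave out. Per the deposited README files, a control alignment entered every list and a further region file, not available here, entered the thresholded lists. The score deposited by the authors for each peak was a scaled form of the IDR, and the lowest in the thresholded lists was 830. The signal deposited by the authors for each peak is the caller's own value, with no unit given. The −log10 q-value deposited by the authors was not used in a test. For both replicates together there were a larger set (5753 peaks) and a conservative set (5709). In the ranked list of the conservative set, the matched peaks equal those of the replicates' own lists, so it compares the replicates. In that of the larger set they do not, and it was read as a comparison of pooled pseudoreplicates. The larger set was the main one. Lists of a single replicate were made from its alignment alone, per the README files, and their matched peaks were read as those of its pseudoreplicates.

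Peak coordinates were compared with the lengths of the dm6 arms, and gene annotation was Ensembl release 115 on that assembly, with soft-masked sequence of the same assembly. Positions are 1-based. Summits on the arms X, 2L, 2R, 3L, 3R and 4 were kept (5750 of 5753). Summits were assigned to a class in the order promoter (500 bp on either side of a transcript start), 5′ UTR, 3′ UTR, coding exon, other exon, intron and intergenic. Random placements (1000) kept the number of summits per arm and avoided unknown bases, except that those for replicate overlap did not avoid unknown bases. Shares carry 95% exact binomial intervals, which cover counting error only. Signals of promoter and other peaks were compared with a permutation test (100000 resamples).

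A gene had a peak when a summit lay within 1000 bp of any of its transcript starts. The 32 gene lists (918 names) and 36 motifs had been fixed before the data were examined. Of the names, 886 matched a gene symbol, 14 an older symbol, and 18 matched no gene and were left out. Each list was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists. Matched lists (10000) were drawn within 5 bins of gene length and 4 classes of the number of transcript starts. Motifs were compared between 200 bp summit windows and flanks 1000 bp away, with flanks within 200 bp of another summit left out, by the same test and adjustment over the motifs.

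The genes named were fixed by a rule. They were Gug, the nearest coding genes of the 10 peaks with the highest signal, up to 4 members of each list with the highest signal near a transcript start, and the 10 coding genes with the most summits. The signal of a named peak in a replicate is that of the peak in its ranked list with a summit at most 100 bp away. Alternatives, fixed in advance, were the conservative set, each replicate's own peaks, an IDR of 0.01 or less, the 1000 strongest peaks, other distances and windows, and matched backgrounds. The first threshold turned out to be the authors' own, so an IDR of 0.001 was added.

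The steps were tested on simulated data. With summits moved to promoters in 20 sets of 5750, 20 were called, and 0 of 20 unchanged sets were. Over 13945 genes, 85.8% of lists raised to a peak share of 60% were called, as were 65.0% of lists set to 0% and 1.14% of unchanged lists. Genes outside the changed lists all had the same chance of a peak, whatever their length or number of transcript starts. False calls from such differences between genes were therefore not tested. Every list called higher in the data had a share below the simulated 60%. For motifs, both sets of windows were drawn from the same shuffled flank windows, so they had no difference in GC content. A planted motif was called in 100% of 5 simulations, and 0% of unchanged motifs were. False calls from a GC difference between summits and flanks were therefore not tested. Loci filled with summits were called in 20 of 20 sets, and 1 of 20 unchanged sets was. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.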

Results

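Gug, also called Grunge or Atrophin, is a Drosophila transcriptional corepressor that binds DNA through other proteins. Chromatin from whole prepupae (1 day) of a fly line carrying Gug fused to eGFP was immunoprecipitated with an antibody to GFP and sequenced in 2 biological replicates. The labels define a single condition, so the comparisons were between replicates, between peak positions and the genome, and between gene groups. The deposited set of peaks from both replicates held 5753 peaks, with a median width of 336 bp (84 to 647 bp) and 1688 kb covered in all. Of these, 5750 had a summit on the arms X, 2L, 2R, 3L, 3R and 4 of dm6. Replicate 1 alone gave 3827 peaks and replicate 2 alone gave 4000. Read depth per library was not given in the sources used here, and the deposited signal of a peak was used only to rank or describe peaks within a list.

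Gug itself, the tagged gene, carried 9 summits from 2000 bp upstream to the gene end (FBgn0010825, arm 3L, 8449922 to 8472669, plus strand). The strongest lay in an intron at 8458316, with a deposited signal of 787 over both replicates, 365 in replicate 1 and 433 in replicate 2. A promoter summit at 8450325, 323 bp from a transcript start, had a signal of 708 (333 and 365 in the replicates), and an intronic summit at 8455623 had 540 (259 and 287). These 3 peaks and an intronic summit at 8459596 (signal 107) were in the thresholded list of each replicate. The other 5 summits were in the list of 1 replicate or of neither, with signals from 13.9 to 102. The weakest, at 8459799, lies beside the summit at 8459596 and had no peak of its own in the ranked list of either replicate. The labels describe an insertion that targets Gug, and the copy number of the locus in the line was not analysed here.

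**Figure D1:**
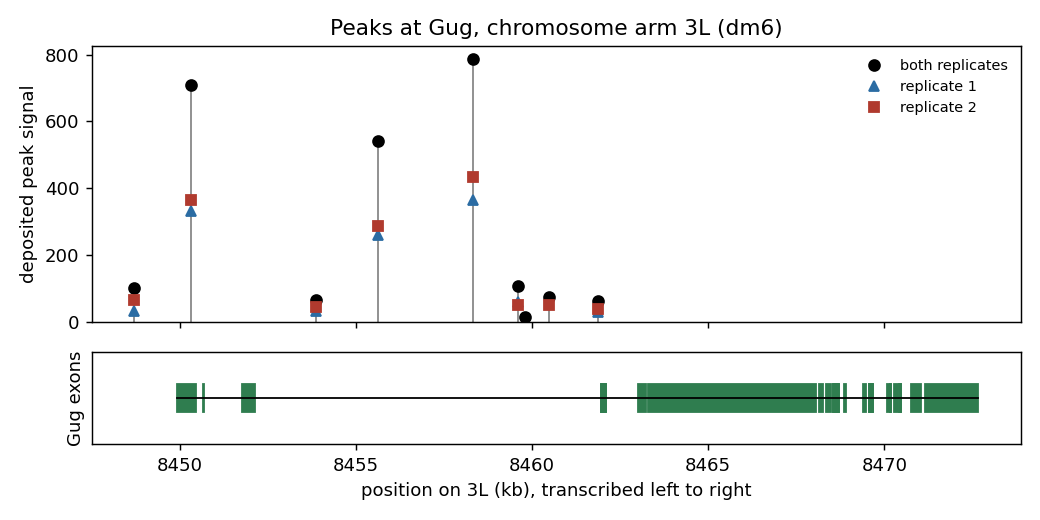
Points are the deposited signals of peaks at Gug on arm 3L (y axis, no unit given) at their summits (x axis, kb) over both replicates (black), in replicate 1 (blue) and in replicate 2 (red), and green boxes below are the annotated exons. The 3 strongest summits, at signals of 787, 708 and 540, lay in the 5′ part of the gene.

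Promoters held 7 of the 10 strongest peaks. The highest signal, 2333, was in an intron of CG11050 at 2L 6612707, followed by 2182 at the promoter of CG14100 (3L 19590615) and 2084 at the promoter of Ugalt, a UDP-galactose transporter (X 2703889). The promoter of mRpL41, a protein of the mitochondrial ribosome, had 1889 (2R 15217756). Promoter peaks near Tcs5 (3L 5139485), Art3, a protein arginine methyltransferase (3R 15229529), and PNPase, the mitochondrial polynucleotide phosphorylase (3R 31404661), had 1643, 1560 and 1511. A peak at an annotated promoter 5075 bp from the nearest coding transcript start, that of CG4004, had 1518. Intergenic summits at 2R 22678385 and 2R 13035341, with signals of 1702 and 1580, had RYBP and CG13323 as nearest coding genes, 7620 and 11915 bp away. All 10 of these peaks were in the lists of both replicates.

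The replicates shared most of their peaks. Of the replicate 1 peaks, 78.1% overlapped a replicate 2 peak by at least 1 bp, against a mean of 1.67% (at most 2.33%) for 1000 random placements. Of the replicate 2 peaks, 74.9% overlapped a replicate 1 peak, against 1.60% (at most 2.23%). The one-sided permutation p was 0.000999 in both directions, the smallest the placements can give. These placements were uniform along each arm and did not keep the excess of summits at promoters. The p therefore shows only that the overlap exceeded that of uniform positions. In the longer ranked list of the other replicate (40805 and 50946 peaks), the shares were 98.6% and 97.6%. No random share was computed for these longer lists. Across the 67232 ranked peaks, Spearman's rho of the signal between replicates was 0.409, and across the 5806 that passed the threshold it was 0.810. The threshold keeps peaks whose ranks match between these replicates, so the higher rho follows in part from the selection. Peaks are not independent replicates, so rho describes these lists and carries no p-value. Between the pseudoreplicates of replicate 1 and of replicate 2, rho past the threshold, selected in the same way, was 0.741 and 0.768.

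Summits were concentrated at promoters, here the 500 bp on either side of any transcript start. They held 2060 of 5750 summits, 35.8% (95% exact interval 34.6 to 37.1), against 13.5% for random placements within the same arms, a ratio of 2.65. Introns held 45.7% against 39.6%. Coding exons held 20 summits, 0.348% against 13.1%, 3′ UTRs 0.626% against 5.06%, and intergenic sequence 16.0% against 27.2%. Each of these 5 classes had p = 0.002 (two-sided permutation test over placements, adjusted p = 0.0028), the smallest the placements can give. 5′ UTRs outside promoters held 0.470% against 0.786% (permutation adjusted p = 0.0186) and other exons 1.10% against 0.808% (permutation adjusted p = 0.026).

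Ranked peaks that failed the threshold had a different distribution. Of 59591 such peaks, 16.9% (16.6 to 17.2) were at promoters and 19% in coding exons, against 35.8% and 0.348% of the thresholded peaks (Fisher's exact test, two-sided, p = 8.2e-233 for promoters). Thresholded promoter peaks also had the higher signal, with a median of 119 against 108 for the 3690 other peaks (permutation test, two-sided, p = 1e-05, the smallest that 100000 resamples can give). Both tests treat peaks as independent units, which they are not. Their p-values describe these lists and do not measure variation between biological replicates. With the peaks ranked by signal and split into 5 equal parts, the strongest part had 44.8% at promoters (41.9 to 47.7) and the others 31.5% to 35.8%.

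**Figure D2:**
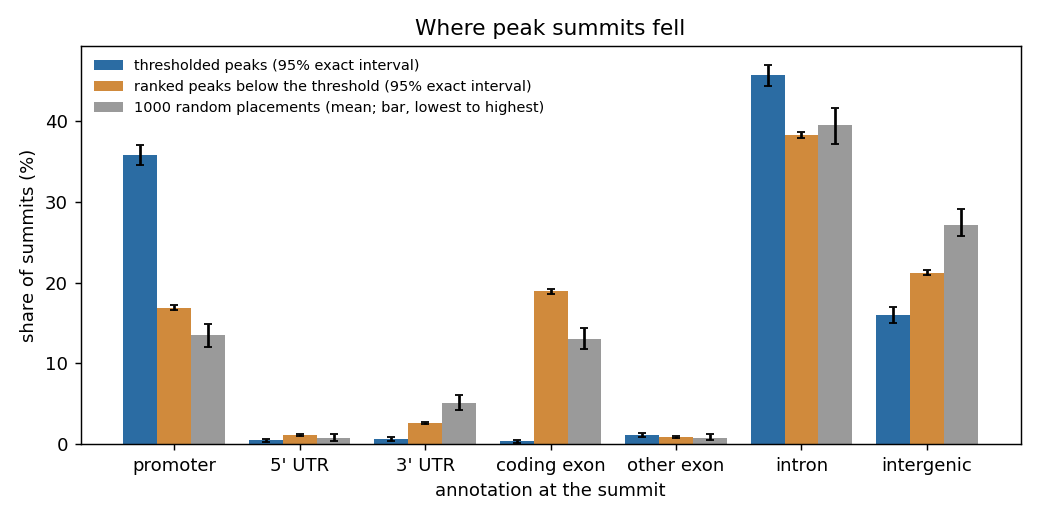
Bars are shares of summits (y axis, %) by annotation class (x axis), blue for the 5750 thresholded peaks and orange for the 59591 ranked peaks below the threshold, both with 95% exact intervals, and grey for the mean of 1000 random placements with their lowest and highest value. Promoters held 35.8% of thresholded summits against 13.5% of random positions, and coding exons 0.348% against 13.1%.

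The X chromosome had 49.2 peaks per Mb (1159 peaks) and the arms of chromosomes 2 and 3 had 42.1, a ratio of 1.17 (95% exact conditional interval 1.10 to 1.25; exact binomial p = 2.9e-06). Replicate 1 alone gave 1.27 and replicate 2 alone 1.15. Among peaks below the threshold the ratio was 1.02 (0.995 to 1.04). Chromosome 4 held 1 thresholded peak, where 57.9 would match its length, and 17 ranked peaks below the threshold. The labels do not give the sex of the prepupae, and the interval covers counting error only.

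A summit lay within 1000 bp of a transcript start for 2638 of 13945 protein-coding genes, or 18.9%. Chemoreceptor, cuticle, germline and glue genes were below that level. Among odorant and gustatory receptors, 1 of 62 genes had a peak (1.61%, Fisher's exact test, two-sided, adjusted over the 32 lists, p = 0.00185), Or88a, at a signal of 113. Among cuticle proteins it was 2 of 50, Cht7 (262) and Cpr64Aa (107), with an exact adjusted p of 0.0168. No peak was near any of 30 male germline genes (exact upper limit 11.6%, adjusted p = 0.0168) or any of 22 genes for glue and salivary secretions (upper limit 15.4%, exact adjusted p = 0.0404). Each list had at most 2 genes with a peak in either replicate alone, but with the fewer peaks of a single replicate only the odorant and gustatory receptors passed the test. The glue and salivary secretion genes did not pass with the conservative set either.

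Peaks were more frequent than at other genes in 7 of the 32 lists, among them 3 of the 7 signalling lists. Lists share members, so these are not all separate results. EcR, usp, Eip75B and other receptors are in both the ecdysone and the nuclear receptor list, and gro is in both the Notch and the corepressor list. Among Fat, Hippo and planar polarity genes, 12 of 26 had a peak (46.2%, exact adjusted p = 0.0112), including the atypical cadherin gene ds (signal 404), crb (324), Diap1, an inhibitor of apoptosis (314), and dlg1 (270). Among Notch pathway genes it was 11 of 26 (42.3%, exact adjusted p = 0.0203), with the corepressor gene gro (599), numb (416), fng (302) and aph-1 (228). Among EGFR and Ras pathway genes it was 10 of 23 (43.5%, exact adjusted p = 0.021), with the ligand genes spi (368) and Krn (170), the repressor gene cic (299) and the EGFR antagonist gene aos (209). Among ecdysone response and metamorphosis genes it was 15 of 34 (44.1%, exact adjusted p = 0.00703), with E23, an ecdysone-induced ABC transporter gene (635), gce, a juvenile hormone receptor gene (410), Ldh (349) and Eip93F (199). Nuclear receptors had peaks at 9 of 21 genes (42.9%, exact adjusted p = 0.0319), with Hr96 (345), ERR (226), Eip75B (153) and Hnf4 (136). Corepressors and histone deacetylases had peaks at 10 of 21 (47.6%, exact adjusted p = 0.0168), with Gug (708), gro (599), CtBP (209) and brk (164). Gug is the tagged locus itself, and the list was not tested without it. Ribosomal proteins had peaks at 29 of 79 genes (36.7%, exact adjusted p = 0.00362), with RpL34b (501.1), RpS20 (266), RpS28b (231) and RpL32 (199). Fat, Hippo and planar polarity genes and Notch pathway genes passed the test in either replicate alone. EGFR and Ras pathway genes passed only in replicate 2, ecdysone response, ribosomal protein and clock genes only in replicate 1, and nuclear receptors and corepressors in neither. Fat, Hippo and planar polarity genes did not pass with the conservative set. The summits named for ds, crb, Diap1, fng, cic, CtBP and brk lay within 1000 bp of a transcript start but outside promoters. With summits within 500 bp of a transcript start, 2 lists were higher.

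Random lists matched on gene length and number of transcript starts had peaks at 20.2% (Notch pathway) to 35.0% (nuclear receptors) of genes for the 6 higher lists other than ribosomal proteins, above the 18.9% of all genes. Against 10000 such lists, ribosomal proteins had peaks more often (36.7% against 18.2%, permutation adjusted p = 0.0128). The matched lists left odorant and gustatory receptors lower (1.61% against 13.6%, permutation adjusted p = 0.0277). Neuronal and synaptic genes were then lower too, at 5 of 37 (13.5% against 35.3%, permutation adjusted p = 0.0277), with elav (615), dnc (548), Sh (147) and Nrx-1 (133) among the 5. None of 16 Hox and homeotic selector genes had a peak near a transcript start, against 29.3% for matched lists (permutation adjusted p = 0.0432), while the exact unmatched test gave an adjusted p of 0.117. In replicate 2 alone, 1 of the 16, cad, had a peak. The other 9 lists called in the unmatched test did not pass, with permutation adjusted p of 0.0539 for the Notch pathway, 0.0539 for male germline genes and 0.155 to 0.835 for the rest.

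Counted from 2000 bp upstream to the gene end, 3588 of 13945 genes held a summit. With this count and with length matched in 20 bins, a combination chosen after the data had been seen, 5 lists stood above matched lists. They included the EGFR and Ras pathway at 18 of 23 genes (78.3% against 44.7%, permutation adjusted p = 0.0141), and Fat, Hippo and planar polarity at 18 of 26 (69.2% against 42.9%, permutation adjusted p = 0.0201). The Notch pathway had 15 of 26 (57.7% against 31.7%, permutation adjusted p = 0.0201), and ecdysone response and metamorphosis had 25 of 34 (73.5% against 51.8%, permutation adjusted p = 0.0328). Ribosomal proteins were also above (38.0% against 21.2%, permutation adjusted p = 0.00853). Muscle structural genes (17.9% against 48.5%, permutation adjusted p = 0.0032), neuronal and synaptic genes (32.4% against 57.3%, permutation adjusted p = 0.0141) and odorant and gustatory receptors (1.61% against 17.9%, permutation adjusted p = 0.0032) were below. The Hox and homeotic selector genes were not (permutation adjusted p = 0.173), with summits in 4 of 16 (25% against 46.2%), among them 11 at hth and 8 at Antp, named after their values were seen.

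**Figure D3:**
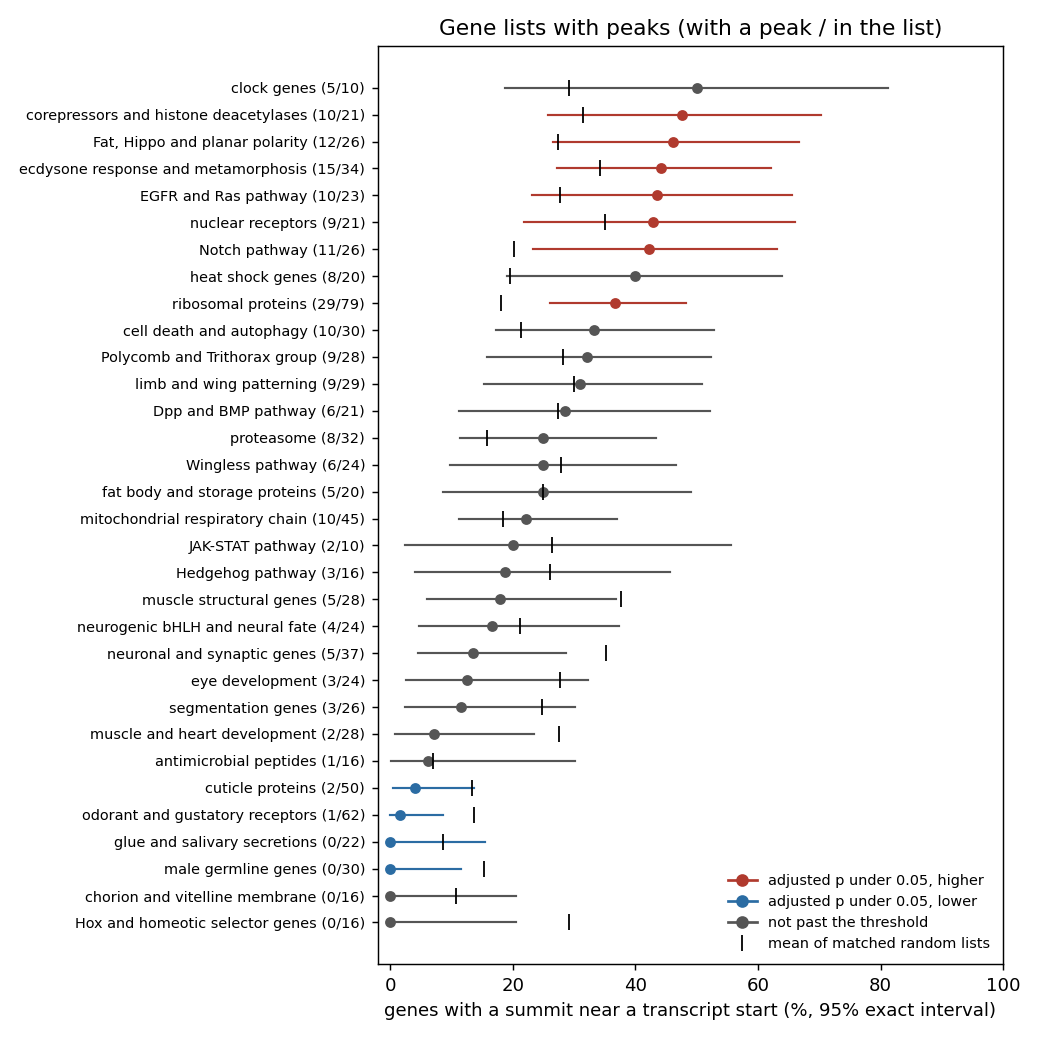
Points are shares of genes with a summit within 1000 bp of a transcript start (x axis, %) for 32 gene lists (y axis, with genes with a peak and genes in the list), with 95% exact intervals, red higher and blue lower than other genes at an adjusted p under 0.05, and black ticks are the means of matched random lists. Ribosomal proteins lay at 36.7% against a matched 18.2%, and odorant and gustatory receptors at 1.61% against 13.6%.

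The remaining lists did not pass the test near transcript starts with the peaks of both replicates together. Some of their members had strong promoter peaks. Others had a summit within 1000 bp of a transcript start but outside promoters. In this paragraph these were wit, Mad, brk, shn, bab2, Stat92E and Socs36E, and in the next bmm, Cyt-c-p, Msp300 and cpo. The peaks of tim and Socs36E, and of cpo, oc, so and Drs in the next paragraph, were in the thresholded list of neither replicate. The Polycomb and Trithorax group had peaks at 9 of 28 genes (32.1%, exact adjusted p = 0.166), including ph-p, a component of Polycomb repressive complex 1 (signal 1470), brm, the ATPase of the Brahma remodelling complex (995), Trl, which encodes GAGA factor (354), and E(z), the histone H3 lysine 27 methyltransferase gene (334). Heat shock genes had 8 of 20 (40%, exact adjusted p = 0.0948), with Hsp27 at 1308, Hsc70-5 at 283 and Hsp26 at 253. Clock genes had 5 of 10 (50%, exact adjusted p = 0.0696), with Pdp1 (207), cry (188), dco (132) and tim (106). Cell death and autophagy genes had 10 of 30 (33.3%), with hid (441), Atg17 (395) and Atg7 (304). Limb and wing patterning genes had 9 of 29 (31.0%), with Dll at 468, bab2 at 126 and btd at 117. In the Dpp and BMP pathway 6 of 21 genes had a peak, with wit (406), Mad (235), brk (164) and shn (123), and in the Wingless pathway 6 of 24, with sgg (442), nkd (156) and Apc2 (105). The JAK-STAT pathway had 2 of 10, Stat92E (173) and Socs36E (12.3). The Hedgehog pathway list, as fixed, had 3 of 16. They were cmb (204), whose place in this pathway was not checked here, slmb (66.0) and Pka-C1 (64.8). The peaks of slmb and Pka-C1 were in the thresholded list of neither replicate.

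Fat body and storage protein genes had peaks at 5 of 20 genes, with Lpin, the lipin phosphatase gene, at 1042, bmm at 188 and Adh at 159. The proteasome had 8 of 32, with Rpn3 at 197, and the mitochondrial respiratory chain 10 of 45, with Cyt-c-p at 554 and levy at 235. Muscle and heart development genes had 2 of 28, tin (353) and org-1 (352), and muscle structural genes 5 of 28, with Msp300 (410) and sls (309). Neurogenic bHLH and neural fate genes had 4 of 24, with elav (615) and cpo (115.1). Segmentation genes had 3 of 26, hb (211), nkd (156) and cnc (144), and eye development genes 3 of 24, dac (102), oc (78.4) and so (71.4). Antimicrobial peptide genes had 1 of 16, Drs (65.7), and chorion and vitelline membrane genes 0 of 16 (exact upper limit 20.6%).

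Peaks also gathered in particular loci. Counting from 2000 bp upstream to the gene end, 231 genes held 5 or more summits, against 123 (103 to 146) in 1000 random placements (two-sided permutation p = 0.002, the smallest they can give). Replicate 1 alone gave 115 such genes against 54.7 at random, and replicate 2 alone 125 against 58.8. Some counts include a weak summit beside a stronger one that shares its matched peak, and without these 192 genes held 5 or more, against 106 at random. The placements were uniform along each arm and did not keep the excess of summits at promoters and introns. Counts of single genes, given next, are raw and were not compared with the count that gene length alone would give. X as a whole held 49.2 peaks per Mb, so a gene as long as kirre holds many by length alone. The largest counts were 26 at sbb (scribbler, 79.1 kb, arm 2R), 25 at kirre (394 kb, X), 23 at CG1677 (125 kb, X) and 22 at Snoo, the Drosophila Ski and Sno family gene (93.0 kb, 2L). Tet held 19 (93.0 kb, 3L), heca 18 (94.5 kb, 3R), the kinase gene Tlk 17 (69.8 kb, X), and shn, a zinc finger gene of the Dpp pathway, 16 (58.3 kb, 2R). Svil (122 kb, 3L) and CG43658 (105 kb, X) held 15 each. The strongest summit of 8 of these 10 genes was intronic, with signals from 431 at kirre to 925 at Tlk, and all 10 were in the lists of both replicates. The summits of CG1677 include those at brk, which lies inside its span.

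Sequence at the summits was rich in A and T. The 200 bp windows around summits had a GC content of 36.6%, against 42.2% in flanks 1000 bp away. Against flanks, 7 of 36 fixed motifs were more frequent and 15 less frequent (Fisher's exact test, two-sided, adjusted p under the 0.05 threshold). Against 11500 random windows of the same class and GC content, 9 were more frequent and 6 less frequent. The TATA box word was in 33.7% of summit windows against 21.0% of flanks, the homeodomain word in 16.1% against 12.8%, the GATA word in 37.3% against 31.1%, the DREF word in 1.27% against 0.502% and the M1BP word in 0.591% against 0.233%. Against the matched windows, none of these 5 passed. The TATA box word was then in 32.2% of controls (exact adjusted p = 0.0932) and the DREF word in 1.07% (adjusted p = 0.338).

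The GAGA factor word GAGAG and the poly A control word were higher against both backgrounds. The control word was in 18.2% of summit windows, 12.1% of flanks and 14.5% of matched windows, with log2 odds ratios of 0.69 against flanks and 0.40 against matched windows. GAGAG was in 24.2% of summit windows (23.1 to 25.3), against 21.6% of flanks (exact adjusted p = 0.000348) and 17.7% of matched windows (adjusted p = 8.43e-22). Against flanks the difference was lost in replicate 1 alone (log2 odds ratio 0.05), in the 1000 strongest peaks (−0.014) and in windows of 100 bp (−0.13). Words for Pho (24.2% against 29.5% of matched windows, exact adjusted p = 1.88e-12), the nuclear receptor monomer site AGGTCA (3.57% against 5.35%, adjusted p = 8.91e-07) and ETS factors (2.92% against 4.43%, adjusted p = 5.48e-06) were lower against both. The Mad word, in 22.3% of flanks, was in 13% of summit windows and in 13% of matched windows.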

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

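The return of these peaks to the set and the resampling of runs were chosen only after the data had been seen, and the tests of CACTG and soft-masked sequence had their outcomes written down before they were run. In the ranked list of both replicates, 104 peaks had an IDR of 0.01 or less and were not in the larger thresholded set. The numbers were 97 for the conservative set, 73 for replicate 1 and 82 for replicate 2. They were singled out because they are signal outside the sets used for the comparisons.

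On the arms there were 102 such peaks, 62 on 3R and 30 on 2L, with a median signal of 122 against 112 for the thresholded peaks. The genes below were chosen after their values were seen. An intronic summit of ush, 1412 bp from a start of cbt (2L 481100), had a signal of 1851 (840 and 1044 in the replicates), and 4 thresholded peaks were stronger. Lk6 followed at 1227 (3R 11761058) and larp at 1159 (3R 28326589). After peaks nearest CG18428, Alh, cbt and tara came trx, the Trithorax gene, at 597 (3R 14283874). The gene tara overlapped 10 of them, and InR, Kdm2, jumu, crp, spen, ush and Pgk overlapped 4 each. Put back into the set, they raised the number of lists called from 11 to 13, with the Polycomb and Trithorax group and the clock genes past the threshold.

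Repeats and a high background are candidate explanations for why these peaks were left out. The median soft-masked share of their 200 bp windows was 17.3%, against 21.0% for thresholded peaks, which gives no sign of an excess of repeats but lies above the 10% set in advance as the bound to exclude them. The word CACTG was in 37.3% of their windows (27.9 to 47.4), against 29.9% of flanks and 49.8% of thresholded peaks. These peaks fall in 44 runs and are not independent, and resampling whole runs gave 27.1 to 48.5, which holds the share of flanks and ends just below that of thresholded peaks. An interval that holds the share of flanks had been written down as the outcome of high background without the peaks' sequence features. It cannot decide here, because on few runs it reaches from below the flanks nearly to the thresholded peaks. Peaks below the threshold had a similar share, 37.4%. Further regions also entered the thresholded lists and were not available here, so whether they removed these peaks could not be examined. Control libraries were not analysed here, no biological explanation was tested, and the strongest of these peaks were present in both replicates.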

How the results depend on the processing

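The IDR of 0.001, the removal of lower-signal neighbours, the return of left-out peaks, the background of failed peaks and the gene count with matched lists were chosen after the data had been seen. The planned IDR of 0.01 removed no peak and says nothing about stability. The promoter excess and the higher promoter signal kept their direction and their side of the threshold under every alternative run, with promoter shares from 23.2% at 200 bp to 46.8% at 1000 bp. Peak count was 3827 to 4000 in single replicates. Replicate overlap was 70.5% and 67.6% with 50% reciprocal overlap, 75.3% and 72.0% with summits at most 100 bp apart, and 83.8% in both directions for the 1000 strongest peaks. Over all ranked peaks, the signal correlation was 0.409 as Spearman's rho and 0.695 as Pearson's r of log2 signal. Past the threshold, rho was 0.810. The X to autosome ratio was 1.15 to 1.27 in single replicates and 1.27 in the 1000 strongest peaks. The number of lists called was 9 with the conservative set, without Fat, Hippo and planar polarity genes and glue genes, and 10 without lower-signal neighbours, where glue genes were lost. It fell from 11 to 4 and 6 in single replicates, 0 in the 1000 strongest peaks, 4 at an IDR of 0.001, 4 with summits within 500 bp and 4 against matched lists. It was 16 with summits from 2000 bp upstream to the gene end, and 8 with that count against matched lists. Genes with 5 or more summits numbered 115 to 125 in single replicates, 8 in the 1000 strongest peaks and 125 at an IDR of 0.001, with 601 genes at 3 summits or more and 42 at 10 or more. Single replicates, the 1000 strongest peaks and the IDR of 0.001 hold fewer peaks by construction. For the other settings the cause was not tested.

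Against windows matched on class and GC content, among motifs that passed the threshold against this background or flanks, log2 odds ratios changed sign for the CA repeat (0.49), CAGCTG (0.35), the Hairy C box (0.40), Brinker (0.22), homeodomain (−0.068), the GC box (0.35), CTCF (0.30) and (AG)5 (1.51). GAGAG changed sign in the 1000 strongest peaks (−0.014) and in 100 bp windows (−0.13), and M1BP (−2.73) and ribosomal proteins (−0.24) in the 1000 strongest peaks. The M1BP word was in only 34 of all 5750 summit windows, so its value in 1000 peaks rests on few windows. For muscle structural genes, the gene count with matched lists gave −1.36, a log2 ratio of counts and not an odds ratio. Their log2 odds ratio near transcript starts was 0.0041, at 17.9% against 18.9% of other genes. That value was close to no difference, so the sign change is not a reversal. The causes of these changes were not tested. For single lists and motifs, 621 alternatives kept their side of the threshold without a sign change of a called value, 73 lost the threshold and 37 passed it. Depth per library was not given, so its limit could not be set.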

Other observations

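The word tests against windows matched on GC content, the families below, the counts without mRpL41 and mRpS10 and the matching of neighbouring peaks were chosen after their patterns had been seen. The outcomes for the position, the repeats and both sides of the summit, for CACTG in neighbours and for mitochondrial ribosomal proteins were written down before those values were computed.

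Gene families outside the fixed lists were taken by symbol, 10 in all. Mitochondrial ribosomal protein genes, tested because mRpL41 was among the strongest peaks, had a summit near a transcript start at 22 of 73 genes, 30.1% (19.9 to 42.0), against 18.9% of other genes (Fisher's exact test, two-sided, adjusted p = 0.0463 over the families). In matched random lists the share was 10.2% (permutation adjusted p = 0.002). The strongest were mRpL41 (signal 1889), mRpS10 (1560), mRpS23 (1400) and mRpL23 (1240), each with a peak in both replicates. The mRpS10 value is that of the peak nearest Art3. Each replicate alone gave 14 genes. Without mRpL41, which prompted the test, 21 of 72 had a summit (29.2%, exact adjusted p = 0.0673), and without mRpS10 as well, 20 of 71 (28.2%, exact adjusted p = 0.133). Neither passed against other genes, while both passed against matched lists (10.2%, permutation adjusted p = 0.002). Whether Gug-GFP peaks favour these promoters stays open, since the answer differed between the backgrounds. Other genes of mitochondrial translation were not tested as a group.

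Families of detoxification and chemoreception had few peaks. Cytochromes P450 had 6 of 85 (7.06% against 17.9% in matched lists, permutation adjusted p = 0.015), ionotropic receptors 1 of 60 (1.67% against 16.8%, adjusted p = 0.002) and UDP-glycosyltransferases 0 of 35 (exact upper limit 10%, against 16.8%, adjusted p = 0.0113). Odorant-binding proteins had 3 of 51 (5.88%), lower than other genes (exact adjusted p = 0.0301) but not than matched lists (11.3%, permutation adjusted p = 0.513). Translation initiation factors (8 of 44), tRNA synthetases (8 of 32), Mediator subunits (6 of 25), TAF and TFII factors (4 of 24) and a set of PHD and bromodomain names (2 of 6) did not differ past the threshold from other genes. The last set was picked by the start of the symbol alone and includes Brd, a gene of the Notch list, so membership does not show either domain. Of 290 tRNA genes, 6.21% (3.72 to 9.63) had a summit within 500 bp, against a mean of 4.61% and at most 8.97% in 200 random placements.

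A 5 bp word that was not among the fixed motifs marked these peaks. On 2L and 2R, CACTG, with its reverse complement CAGTG, had the smallest p of all words of 5 and 6 bp, in 50.6% of summit windows against 23.9% of windows matched on class and GC content. On X, 3L and 3R the shares were 49.4% (47.8 to 51.0) and 24.9%, a log2 odds ratio of 1.56 (1.44 to 1.68). The word had been seen on all arms before this split, so X, 3L and 3R are not independent evidence. It was higher in promoter peaks (44.1% against 26.0%) and in other peaks (53.0% against 23.7%), in replicate 1 (50% against 29.9% of flanks) and in replicate 2 (51.1% against 30%). In a sample of 10000, peaks below the threshold had 37.4% against 30.7%.

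The word was not at the summit, which for 79.5% of peaks was the middle of the peak. A 40 bp window centred on the summit held it in 6.33% of peaks, a difference of −1.43 percentage points from windows 200 bp away, where a rise of 5 had been written down as the outcome of a central site. The share rose to 16.6% at 80 bp to the left and 16.3% at 80 bp to the right. Peaks with the word 40 to 120 bp to the left held it on the right in 35.3%, against 25.6% of other peaks, a log2 odds ratio of 0.67 (0.49 to 0.84). Among the 1000 strongest peaks these shares were 49.7% and 31.0%, and at flank positions 13.7% and 12.6%.

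These values argue against GC content as the whole cause, from the 1.56 above. The windows were matched on GC content and class only, so other features of base composition were not excluded. The CA repeat was also higher against such windows (4.28% against 3.10%). The values argue against repeats as the whole cause, since outside soft-masked bases the log2 odds ratio against flanks was 0.92 (0.82 to 1.01), lower than the 1.22 (1.13 to 1.32) of all bases against flanks but above 0. They also argue against a single site on 1 side of a displaced summit, which would give a log2 odds ratio below 0 between the sides, not 0.67. An effect of sequence at fragment ends stays open, because reads were not analysed here. At 80 bp to the left, CACTG was in 9.53% of windows and CAGTG in 7.48%, and on the right in 7.30% and 9.37%. Both orientations were thus present on both sides, with CACTG the more frequent on the left and CAGTG on the right. This mirrored difference was not tested. What places the word on both sides was not tested.

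Some peaks had a weak neighbour at a nearly fixed distance. Among 5750 peaks there were 442 such lower-signal neighbours. Of 444 pairs of summits at most 300 bp apart, 373 were 180 to 220 bp apart, and none was closer than 199 bp. The median signal was 12.2 for the lower peak and 98.3 for the higher, against 112 for all thresholded peaks. In 96.8% of pairs (94.8 to 98.3) the lower peak shared its matched pseudoreplicate peak with a stronger one, which suggests that 1 peak passed the threshold several times through the matching. CACTG was in 47.3% of the lower neighbours (42.5 to 52.1) and in 50% of the other peaks, so separate sites cannot be told apart from the matching by this word, because neighbouring windows adjoin.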
